A study of Oryza sativa Indica Group with 4 samples.

How the data were processed

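Gene expression was measured in leaves of the Indica rice lines TW16-4 and TW16-69 on 4 Agilent 22K oligonucleotide arrays, 2 per line. Each array carried RNA of plants inoculated with rice tungro spherical virus (RTSV) in 1 dye and RNA of mock-inoculated plants in the other. Per the labels, leaves of 5 plants were pooled for each sample, RNA was isolated with TRIzol, amplified with a low-input linear amplification kit and labelled with Cy3 or Cy5. The infected sample was in Cy5 on both TW16-69 arrays and on the replicate 1 array of TW16-4, and in Cy3 on the replicate 2 array of TW16-4, so TW16-4 had a dye swap and TW16-69 had none. The labels describe the replicates as independently grown.

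The authors scanned the arrays and read them with Agilent Feature Extraction. The submitters' notes give version 8.1.1.1 and the scanner settings in the file headers give A.6.1.1, and which one applies to which step is not stated. Per the file headers, the mean spot signals and the median local backgrounds of each channel are intensity values with no background subtracted, and the spot flags (of unit other) are 0 or 1 marks set by the software. The deposited log ratio of each spot is log10 of Cy5 over Cy3 after background subtraction and dye normalization by Feature Extraction. The deposited value table is also in log10. Its direction is not stated, but under the dyes in the labels each of its columns equals log10 of mock over infected, with 98.6% to 99.8% of values within 0.001 of the deposited log ratio of the same array, taken with either sign, and a Pearson r of -1.00 across probes with that log ratio turned to infected over mock. Signs in this text are the opposite, infected over mock.

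Each array held 22575 spots, of which 21495 were gene probes, each with its own full-length cDNA accession and a description by sequence similarity. None of the accessions could be placed on a genome with the reference table at hand, so probes are named by accession and description and no coordinates are given. Median spot signals ranged from 193 to 216 in Cy3 and from 222 to 297 in Cy5 over the arrays, with median local backgrounds of 44 to 69, and 93.6% to 97.2% of gene probes were well above background in a channel. Arrays give no counts, and their number limits the precision.

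The mean signals were corrected with the median local background by the normexp method (offset 50) and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Each log2 ratio was turned to infected over mock by the dyes in the labels. A probe was tested when at least 1 channel was well above background on at least 2 arrays and no spot was marked as an outlier on any of the 4 arrays, which left 20715 probes, 12293 of them with an informative description. Signals at the scanner limit were kept, and 38 tested probes reached that limit on some array.

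A limma model with 1 mean per line was fitted to the 4 log2 ratios of each probe with lmFit and eBayes, with 2 residual and 3.79 prior degrees of freedom. The comparisons were the response of each line, the mean of both responses, the difference TW16-69 minus TW16-4 in response, and the line difference in overall level, which used the average log2 signal of both channels after quantile normalization between arrays. Tests were two-sided and a probe was called at a Benjamini-Hochberg adjusted p under 0.05. Errors after ± are the SD over arrays, and those marked SE are limma standard errors unless stated otherwise. Gene lists fixed from the descriptions were tested with camera at a preset inter-gene correlation of 0.01 when they held at least 5 tested genes, and adjusted over the lists of a comparison. A list held only probes whose description matched its words. Probes of the same family described in other words, or only by a locus or clone number, could be missed. The 34 lists tested cover hormones, defence, cell wall, photosynthesis, protein turnover, metabolism and signalling, and include markers of dividing cells, vascular tissue, epidermal wax, seed storage and photosynthetic mesophyll.

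The lists, tests, alternatives and the naming rule were chosen before the data were examined. Named for a comparison were, among described probes past the threshold with the same sign on all arrays, the 10 with the largest rise and the 10 with the largest fall in log2. For TW16-69 the sign also had to hold with a dye term. Where fewer passed in a direction, those were named and then the smallest unadjusted p of that direction up to 5 in all, given as values. Up to 4 members of each list described were added by smallest unadjusted p, and 3 fixed single genes. Probes named outside the rule are marked as such.

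The arrays carry replicate number 1 or 2, and per the file headers the replicate 1 arrays of both lines were read on 1 day and the replicate 2 arrays on another. A block for replicate number is therefore also a block for processing day, and where it changed a call of a result its values are given beside it. For a response, the block takes the difference between the 2 replicates out of the error. Its p values then measure how alike the lines were within a day, and not whether a response repeated across replicates. The other alternatives tried were the deposited log ratios, no background correction, median centring, scaling between arrays, other filters, a dye term for each probe, each line alone, leaving out each array, another threshold, single-channel analysis with statmod 1.5.0, and set tests with an estimated correlation or with fry. With an estimated correlation camera has only the 2 residual degrees of freedom and little power. Pathogenesis-related proteins in TW16-4 had an estimated correlation of 0.0101, near the preset 0.01. Their unadjusted camera p was 0.114 with the estimate and 0.0068 with the preset. A miss in that test therefore does not show that correlation among genes made a call. For the photosynthesis list in TW16-4, which was called, the estimate was 0.0926, above the preset. Correlation among its genes may have contributed to that call.

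The procedure was tested on simulated data with the fitted spread, 20715 probes and 50 changed probes per size. Errors were drawn independently for each probe and array, with no effect shared by a day or a dye. In the data, ratios of the lines were correlated across probes on each day (Spearman 0.61 for replicate 1 and -0.68 for replicate 2). The rates below therefore hold for independent errors and may differ in these data. The mean response recovered 92% of changes of 1 log2 with 8 false calls in all, and TW16-4 and TW16-69 alone recovered 64% and 66%. The difference in response recovered 8% at 1 log2 and 90% at 2 log2, and the level comparison 0% at 2 log2. With the replicate block, which leaves 1 residual degree of freedom, the mean response recovered 98% at 1 log2 with 24 false calls and the level comparison 100% with 25, so counts from that fit may hold more false calls than the threshold states. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.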

Results

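The series compared leaves of rice infected with RTSV, a leafhopper-borne virus of the tungro disease complex, with mock-inoculated leaves in the lines TW16-4 and TW16-69. Per the labels, seedlings received 3 viruliferous green leafhoppers each for 24 hours, mock plants received virus-free leafhoppers, and the youngest leaves were taken 7 days after inoculation. Each line had 2 arrays, and each array set 1 infected pool of 5 plants against 1 mock pool. All log2 values below are infected over mock, the opposite sign of the deposited value table, and n counts arrays.

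A small group of probes rose strongly on every array, against a background of small ratios that did not repeat between days. Of 20715 probes, 36 were at least 2-fold higher in infected leaves on all 4 arrays and 0 were at least 2-fold lower. On both arrays of TW16-4, 43 probes were 2-fold higher, 0 were 2-fold lower and 2 went 2-fold in opposite directions. On both arrays of TW16-69, 51 probes were 2-fold higher, 3 were 2-fold lower and 1 went in opposite directions. Across all probes, which are not independent replicates, the Spearman coefficient between the replicates was 0.0056 in TW16-4 and -0.0018 in TW16-69. Between the lines it was 0.61 on the replicate 1 arrays, which shared a day and the same dyes, and -0.68 on the replicate 2 arrays, which shared a day and had opposite dyes.

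**Figure D1:**
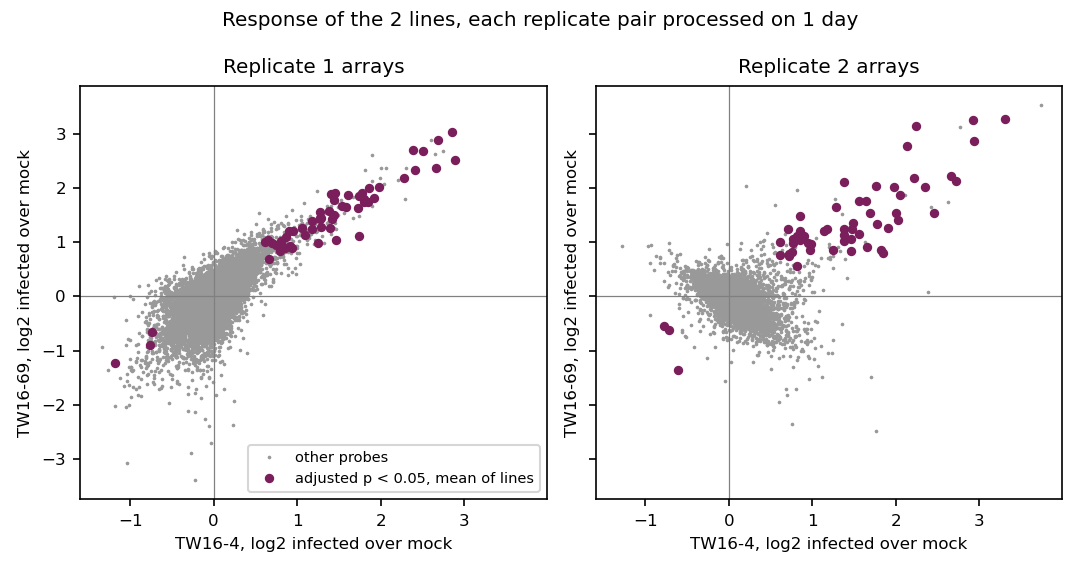
Each point is a probe, with its log2 ratio of infected over mock in TW16-4 on the x axis and in TW16-69 on the y axis, for the replicate 1 arrays (left) and the replicate 2 arrays (right). Purple points are the 56 probes called in the mean of both lines, which had the same sign on all 4 arrays; grey points are the other tested probes.

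The mean response of both lines asked which genes changed with infection in the lines together. Probes described as transcription factors or DNA-binding proteins were among the largest rises. The putative DRE-binding protein 1B (AK062422), of a family that binds the drought and cold response element, rose by 2.83 ± 0.53 log2 (SD, n = 4; 7.12-fold, limma adjusted p = 0.0138). DRE-binding protein 1A (AK105599) rose by 2.51 ± 0.69 (adjusted p = 0.0384 in limma). OsNAC3 (AK067690), a NAC domain transcription factor, rose by 1.99 ± 0.27 (limma adjusted p = 0.0081), and a homologue of an oat DNA-binding protein of clone ABF2 (AK058773) rose by 2.60 ± 0.33 (limma adjusted p = 0.0064). A probe described as a homologue of a tobacco regulator of gene silencing (AK062671) rose by 2.07 ± 0.51 (limma adjusted p = 0.0351).

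Other probes among the 10 largest described rises were homologues of the Arabidopsis transcripts At2g27690 (AK106404, 2.70 ± 0.40 log2) and AT4g34410 (AK062882, 2.70 ± 0.39). A tobacco allyl alcohol dehydrogenase homologue (AK109382) rose by 2.15 ± 0.52 and a homologue of the morning glory transcript PnFL-2 (AK061602) by 2.10 ± 0.53. A homologue of an Arabidopsis cDNA clone (AK062711) rose by 2.00 ± 0.02, with the smallest adjusted p of the comparison (0.0036 in limma). The described fall was a probe for a putative protein kinase similar to At2g30040 (AK108043), which fell by 0.75 ± 0.12 log2, or 1.68-fold (limma adjusted p = 0.0452). The lower values that came next did not pass the test. These were a probe similar to pea chloroplast ribosomal RNA (AK060089) at -0.77 ± 0.30 (adjusted p = 0.0644 in limma, 0.0133 with the replicate block and 0.0380 without TW16-69 replicate 2) and a soluble acid invertase homologue (AK072245) at -0.49 ± 0.20. The chloride channel homologue CLC-Nt2 (AK101523) was at -0.44 ± 0.23 and an AP2 domain protein (AK105877) at -0.44 ± 0.16. Outside the naming rule, and chosen after their values were seen, the other 2 falls were the undescribed probes AK062691 (-1.09 ± 0.33) and AK063206 (-0.68 ± 0.10). Their adjusted p were 0.127 and 0.135 without TW16-69 replicate 1, 0.0670 and 0.0561 without TW16-69 replicate 2 and 0.0950 and 0.266 without TW16-4 replicate 1, and AK063206 was at 0.235 without TW16-4 replicate 2. With the deposited log ratios they were at 0.0921 and 0.134.

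In all, 56 probes were called in the mean response, 53 higher and 3 lower, and 755 had an unadjusted p under 0.05. This fit took the 4 arrays as independent, but arrays of the same day could deviate together. DRE-binding protein 1B was at 2.41 and 2.34 on the replicate 1 arrays of TW16-4 and TW16-69, and at 3.31 and 3.27 on the replicate 2 arrays. For such probes the 4 arrays are not 4 independent values, and the limma p values of the mean response may be too small. Of the 56, 43 changed at least 2-fold and 19 had no informative description. With the replicate block 218 were called, including all 56, and with the dye term 30 were called, 28 of them among the 56. For the mean response the dye term gives the same result as leaving out TW16-4 replicate 1, so these fits are 1 check. The count was 30 without TW16-4 replicate 1, 30 without TW16-4 replicate 2, 21 without TW16-69 replicate 1, 90 without TW16-69 replicate 2 and 24 with the deposited log ratios. The homologues AK106404, AK062882, AK058773 and AK062711 and OsNAC3 passed in every one of these fits, while DRE-binding protein 1B missed only with the deposited log ratios (adjusted p = 0.122). DRE-binding protein 1A missed without TW16-4 replicate 2 (adjusted p = 0.0723) and with the deposited log ratios (0.168). AK109382 and AK061602 missed with the dye term (0.0624 and 0.0629), without TW16-4 replicate 1 (the same values) and without TW16-69 replicate 1 (0.0866 and 0.0861). AK062671 missed without either TW16-69 array (0.115 and 0.0605 for replicates 1 and 2) and with the deposited log ratios (0.134). Of the fits that left out an array, AK108043 passed only in that without TW16-69 replicate 2 (0.0404), and it missed with the dye term (0.279) and the deposited log ratios (0.205). With the dye term limma called 0 falls, with 311 probes of either direction at an unadjusted p under 0.05. Scaling between arrays also lost DRE-binding protein 1A (limma adjusted p = 0.0839) and AK062671 (0.0780), while the other named calls passed. AK108043 also missed with median centring (0.0627) and with outlier-marked spots kept (0.0562).

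**Figure D2:**
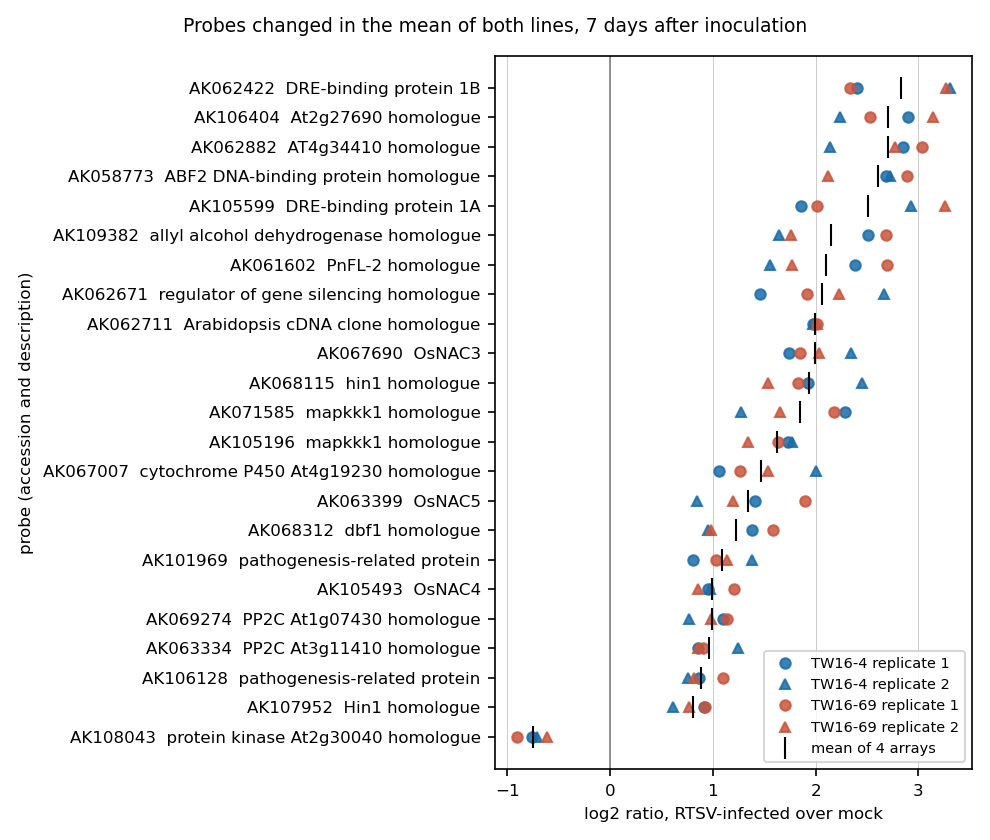
The log2 ratio of infected over mock (x axis) is shown for 23 described probes called in the mean response (y axis), with 1 symbol per array and a vertical tick at the mean of 4 arrays. DRE-binding protein 1B has the largest mean, 2.83, and the protein kinase homologue AK108043 is below 0 on all 4 arrays.

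Defence and signalling probes were also among the 56. Of 90 tested pathogenesis-related proteins, 2 rose and 0 fell, over all probes and adjusted over the list alone. AK101969 rose by 1.09 ± 0.24 log2 (n = 4, limma adjusted p = 0.0386) and AK106128 by 0.88 ± 0.15 (limma adjusted p = 0.0337). A chitinase homologue (AK106178) was at 0.37 ± 0.25 and a thaumatin-like protein (AK069182) at 0.24 ± 0.14. The list did not shift as a whole (median -0.0020 against a mean of 0.03 log2, camera adjusted p = 0.479). Of 34 abscisic acid and dehydration genes, 1 rose, the protein phosphatase 2C AK063334 (0.96 ± 0.19, limma adjusted p = 0.0337), a member of a family known to hold back abscisic acid signalling. Adjusted over the list alone, 2 rose. Its other members included a Lea14-A homologue (AK061818) at 0.51 ± 0.20 and WSI76 (AK071812) at 0.53 ± 0.45, and the list gave a camera adjusted p of 0.206. The cytochrome P450 list took 107 genes by their description, so homologues described only by a locus number were not in it. Of these 107, 1 rose, the homologue of At4g19230 (AK067007, 1.47 ± 0.41, limma adjusted p = 0.0461). Adjusted over the list alone, 1 was called (camera adjusted p = 0.402 for the list). The calls of these 4 genes were lost without TW16-69 replicate 1 (adjusted p from 0.0954 for AK106128 to 0.147 for AK067007) and without TW16-4 replicate 2 (from 0.0503 for AK067007 to 0.114 for AK106128), and with the deposited log ratios (from 0.150 for AK106128 to 0.174 for AK067007). With the dye term AK106128 (limma adjusted p = 0.165) and AK063334 (0.0629) were lost, as they were without TW16-4 replicate 1. Without TW16-69 replicate 2, AK101969, AK063334 and AK067007 were lost. With scaling between arrays AK101969 (0.0779), AK063334 (0.0510) and AK067007 (0.105) were lost, while AK106128 passed (0.0119). AK067007 was also lost with outlier-marked spots kept (0.0587) and with no filter on dim probes (0.0502).

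Further defence and signalling probes among the 56 were outside the naming rule and chosen after their values were seen. A hin1 homologue (AK068115), of a family first described as induced by bacterial harpin, rose by 1.94 ± 0.38 log2, and the rice Hin1 homologue AK107952 rose by 0.80 ± 0.15. The mapkkk1 homologues AK071585 and AK105196, named as kinases at the head of a MAP kinase cascade, rose by 1.85 ± 0.47 and 1.62 ± 0.19. OsNAC5 (AK063399) rose by 1.34 ± 0.44 and OsNAC4 (AK105493) by 1.00 ± 0.15. The maize dbf1 homologue AK068312 rose by 1.23 ± 0.31, EL2 (AK063743) by 1.01 ± 0.20 and a protein phosphatase 2C similar to At1g07430 (AK069274) by 1.00 ± 0.16. Over these 9 probes the limma adjusted p ran from 0.0064 (AK105196) to 0.0484 (OsNAC5). Without TW16-69 replicate 1, OsNAC5 had an adjusted p of 0.115, OsNAC4 0.0673, AK068312 0.109, AK071585 0.125, AK107952 0.151, AK069274 0.109 and EL2 0.120. Without TW16-4 replicate 1 or with the dye term OsNAC4, OsNAC5, AK068312, AK107952, AK069274 and EL2 ran from 0.109 to 0.240. Without TW16-4 replicate 2 the same 6 probes ran from 0.0503 (EL2) to 0.106 (AK107952), and without TW16-69 replicate 2 EL2 (0.0605) and AK107952 (0.0586) missed. With the deposited log ratios the 6 ran from 0.0559 (EL2) to 0.155 (OsNAC5).

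Calcium signalling was the 1 list of 34 that shifted in the mean response, upward, with 57 of its 79 genes above 0 and a median of 0.06 log2 (camera adjusted p = 0.0083). It gave an adjusted p of 0.864 with an estimated correlation, 0.0040 with the replicate block, 0.0303 with the dye term and 0.0935 without TW16-69 replicate 1. The list medians were 0.0754 and 0.1368 on the replicate 1 arrays of TW16-4 and TW16-69, and 0.0073 and 0.0412 on the replicate 2 arrays. Both replicate 1 arrays had the infected sample in Cy5, so a bias shared by them cannot be told apart from a response. No member passed the test for single genes, over all probes or adjusted over the list alone. Calmodulin CaM1 (AK059756), a calcium sensor, was at 0.59 ± 0.20 log2 (adjusted p = 0.148 in limma, and 0.0421 with the replicate block). The calcium-dependent protein kinase homologues AK068315 and AK070346 were at 0.48 ± 0.26 and 0.47 ± 0.29. The EF-hand protein CCD1 homologue AK111852 was at 2.42 ± 1.41 (limma adjusted p = 0.417, and 1.74e-04 with the replicate block). AK111852 was at 1.30 and 1.12 on the replicate 1 arrays of TW16-4 and TW16-69 and at 3.74 and 3.54 on the replicate 2 arrays.

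The remaining hormone and defence lists did not shift in the mean response, and their members are given as values. In the gibberellin list (16 genes, camera adjusted p = 0.206; 0 called over all probes and 2 adjusted over the list alone), GIGR2 (AK073470) was at 0.63 ± 0.34 log2 and the gibberellin-inactivating OsGA2ox3 (AK108802) at 0.89 ± 0.44. CIGR1 (AK069266) was at 0.31 ± 0.28 and gibberellin C-20 oxidase (AK061017) at -0.20 ± 0.28. Among 104 heat shock proteins and chaperones (camera adjusted p = 0.206; 0 called, and 1 adjusted over the list alone), the heat shock protein homologue AK066844 was at 0.92 ± 0.38 (limma adjusted p = 0.0579). The DnaJ homologue AK061049 was at 0.53 ± 0.28 and a heat shock transcription factor homologue (AK101182) at 0.70 ± 0.44. Among the 28 probes described as WRKY factors, 0 were called by either adjustment (camera adjusted p = 0.402 for the list). Homologues of WRKY69 (AK060018), WRKY50 (AK108522), oat WRKY3 (AK110587) and WRKY6 (AK105509) were at 0.59 ± 0.28, 0.30 ± 0.14, 0.72 ± 0.53 and 0.60 ± 0.46. In the jasmonate list (33 genes, camera adjusted p = 0.627), allene oxide synthase (AK068620) was at 0.93 ± 0.51 and an OPR3 homologue (AK071203) at 0.27 ± 0.25. In the ethylene list (30 genes, 0.396) OsEIL2 (AK060806) was at 0.55 ± 0.39 and osERF3 (AK069262) at 0.46 ± 0.33. The argonaute homologue AK060907 of the RNA silencing list (8 genes, camera adjusted p = 0.479) was at -0.22 ± 0.28. With the replicate block 9 of these genes passed: GIGR2 (adjusted p = 0.0212), OsGA2ox3 (0.0110), AK066844 (0.0050), AK061049 (0.0421), AK101182 (0.0337), AK060018 (0.0319), AK110587 (0.0123), AK105509 (0.0304) and allene oxide synthase (0.0052). These block values do not show that a response repeated across the replicates. The other lists, on growth, metabolism, translation and protein turnover, had camera adjusted p from 0.206 (senescence and protein breakdown) to 0.905 (glutathione S-transferases). Without TW16-69 replicate 2, cytosolic ribosomal proteins (4.35e-04) and peroxidases (0.0092) passed downward. Ribosomal proteins passed upward without TW16-69 replicate 1 (0.0250), and the Calvin cycle list passed downward without TW16-4 replicate 2 (0.0321).

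Markers of other cell types, which could show a different tissue mix in infected leaves, did not pass the set test in the mean response. Their medians were -0.01 log2 for 63 histone and cell cycle genes (camera adjusted p = 0.654), 0.04 for 5 phloem and xylem genes (0.688), -0.08 for 23 epidermal wax genes (0.281), -0.03 for 15 seed storage genes (0.402) and -0.04 for 28 photosynthesis genes (0.688). The epidermal wax list passed downward with the dye term (camera adjusted p = 0.0303), without TW16-4 replicate 1 (the same value) and without TW16-69 replicate 2 (0.0043), and photosynthesis, with 9 members saturated on some array, passed downward without TW16-4 replicate 2 (0.0321). Of the fixed single genes, the translation initiation factor eIF4G (AK062438) was at -0.28 log2 and AK069301 at 0.04, neither past the test, and AK064178, a petunia nam-like homologue taken only by its name pattern, at 7.00e-04. The signs of AK069301 and AK064178 turned under other normalizations, to -0.0163 with median centring for AK069301 and to -0.0079 without background correction and -0.0013 with scaling for AK064178.

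**Figure D3:**
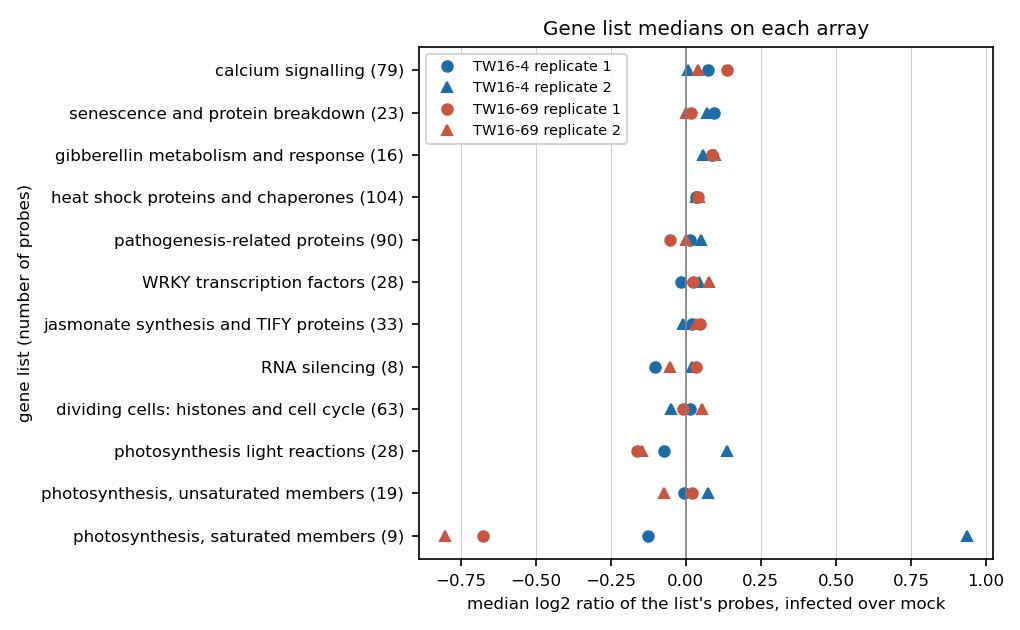
The median log2 ratio of infected over mock (x axis) is shown for gene lists (y axis, number of probes in parentheses), with 1 symbol per array. Photosynthesis is also split by whether a probe reached the scanner limit on any array: the 19 unsaturated members have medians from -0.07 to 0.07. Of the 9 saturated members, 4 were at the limit in both channels on all 4 arrays and 5 in fewer, so their medians are not measured folds.

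In TW16-4, 11 probes rose with infection and 0 fell, with 408 at an unadjusted p under 0.05. The described ones were AK058773 (2.70 ± 0.03 log2, SD, n = 2), AK106404 (2.57 ± 0.47), AK062882 (2.50 ± 0.50), the hin1 homologue AK068115 (2.19 ± 0.38), OsNAC3 (AK067690, 2.04 ± 0.43), AK062711 (1.98 ± 0.0016) and the mapkkk1 homologue AK105196 (1.75 ± 0.03). Their limma adjusted p ran from 0.0280 to 0.0491. All 11 were among the 56 of the mean response. Lower values that did not pass were AK060089 at -0.97 ± 0.05, AK108043 at -0.74 ± 0.03, AK101523 at -0.62 ± 0.10, AK067950 at -0.56 ± 0.34 and a maize ferredoxin VI homologue (AK069860) at -0.51 ± 0.12, of which AK060089 passed with the replicate block (adjusted p = 0.0425). With that block 84 were called (83 higher), with the deposited log ratios 0, with outlier-marked spots kept 1, with no filter on dim probes 2 and with scaling between arrays 24. Among the described probes named above, AK106404 (limma adjusted p = 0.0523) and OsNAC3 (0.0833) missed with scaling and the others passed. Without TW16-4 replicate 1 or replicate 2 the count was 0, and adjusted p of these 7 probes ran from 0.132 to 0.210 and from 0.203 to 0.350. Without either TW16-69 array AK062882 (0.0508) and OsNAC3 (0.0581) missed. Adjusted over the list alone, 2 pathogenesis-related proteins, 1 gibberellin gene and 1 abscisic acid gene passed in TW16-4.

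The senescence and protein breakdown list shifted upward in TW16-4, with 14 of 23 genes above 0 and a median of 0.10 log2 (camera adjusted p = 0.0445, and an adjusted p of 0.820 with an estimated correlation). No member passed alone, over all probes or adjusted over the list alone. The SAG12 homologue AK072767, a senescence-linked protease, was at 0.39 ± 0.13 log2. A cysteine proteinase inhibitor (AK073275) was at 0.32 ± 0.05, a cysteine proteinase (AK063422) at 0.29 ± 0.20 and senescence-associated protein SA5 (AK065366) at 0.22 ± 0.06. The list had an adjusted p of 0.396 without TW16-4 replicate 1, 0.0973 without TW16-4 replicate 2, 0.0163 with the replicate block, and 0.0744 without saturated probes. The photosynthesis list, whose members make up the light-harvesting machinery, also shifted upward in TW16-4 (28 genes, median 0.11 log2, 0 called by either adjustment, camera adjusted p = 0.0445). Its camera adjusted p was 0.820 with an estimated correlation, which was 0.0926 against the preset 0.01. Of its members, 9 were at the scanner limit on some array. Without saturated probes its adjusted p was 0.423 and without TW16-4 replicate 2 it was 0.665 with the direction turned. The photosystem II 10 kDa polypeptide AK103688, which was not saturated, was at 0.24 ± 0.06. Without TW16-4 replicate 1, Calvin cycle (0.0051) and pathogenesis-related (0.0322) lists passed upward. Calcium signalling passed upward with the replicate block (0.0244), without TW16-4 replicate 2 (0.0336) and without either TW16-69 array (0.0476), where ethylene genes passed upward and peroxidases downward at the same value.

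In TW16-69, 3 probes rose with infection and 0 fell, with 1149 at an unadjusted p under 0.05. They were AK062882 (2.91 ± 0.19 log2, SD, n = 2, limma adjusted p = 0.0405), AK062711 (2.02 ± 0.0026, limma adjusted p = 0.0250) and the undescribed probe AK107937 (1.89 ± 0.02, limma adjusted p = 0.0405). The last was chosen after its value was seen. All 3 were also called in TW16-4. Higher values that did not pass were AK106404 at 2.84 ± 0.43, AK058773 at 2.50 ± 0.54 and AK105196 at 1.49 ± 0.21. Lower values that did not pass were a receptor-like kinase RLK4 homologue (AK111650) at -1.16 ± 0.32 and a lysophospholipase homologue (AK112115) at -0.88 ± 0.28. A tobacco tumor-related protein homologue (AK106334) was at -0.86 ± 0.30, AK108043 at -0.76 ± 0.20 and the invertase AK072245 at -0.62 ± 0.10. With the replicate block AK106404 (adjusted p = 0.0054), AK058773 (0.0034), AK105196 (0.0072), RLK4 (0.0143) and AK106334 (0.0403) passed. AK106404 also passed without either TW16-4 array (0.0341) and AK058773 without TW16-69 replicate 2 (0.0305).

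Both TW16-69 arrays carried the infected sample in Cy5. A dye term could be taken only from the TW16-4 swap, where dye ran with replicate and day. It therefore also subtracts any true difference between the TW16-4 replicates. It further takes a probe's bias as equal on all arrays, while Cy5 over Cy3 had a Spearman coefficient of -0.0018 between the TW16-69 arrays. With this term 0 probes were called (196 at an unadjusted p under 0.05). AK062882 was then at 2.55, AK062711 at 2.02 and AK107937 at 2.03 log2, each at an adjusted p of 0.187. The count was 166 with the replicate block (118 higher, 48 lower), 0 with the deposited log ratios and with scaling between arrays, 1 with outlier-marked spots kept and 12 with median centring. It was 7 without either TW16-4 array, 0 without TW16-69 replicate 1 and 11 without TW16-69 replicate 2, where AK062882 and AK107937 each had an adjusted p of 0.0735. No list shifted at the threshold, and 2 pathogenesis-related proteins, 1 abscisic acid gene and 1 heat shock gene passed adjusted over the list alone. Calcium signalling had a median of 0.05 and 58 of 79 genes above 0 (camera adjusted p = 0.0697, and 0.0326 with the replicate block), and photosynthesis had a median of -0.14 (0.0697 and 0.0326). Without either TW16-4 array calcium signalling (0.0377) passed upward, and photosynthesis (3.45e-04) and the Calvin cycle (0.0294) downward. Cytosolic ribosomal proteins passed upward (0.0014) and photosynthesis downward (0.0252) without TW16-69 replicate 1. Without TW16-69 replicate 2, ribosomal proteins (3.26e-05), peroxidases (0.0308) and epidermal wax genes (0.0058) passed downward and calcium signalling upward (0.0308). The 19 members of the photosynthesis light reactions not saturated on any array had medians of 0.02 and -0.07 on the replicate 1 and 2 arrays, and without saturated probes that list had an adjusted p of 0.842, and 0.830 with the replicate block.

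The test of the difference in response between the lines called 0 probes in limma, with 524 at an unadjusted p under 0.05, and 0 with the replicate block or the dye term. The described probes of smallest unadjusted p with TW16-69 above TW16-4 were an adenosine deaminase homologue (AK072514) at 0.92 log2 (SE 0.23, n = 4) and ferritin (AK106026) at 0.77, with an ankyrin homologue (AK111573) at 0.65, AK058684 at 0.63 and the sugar transporter homologue STP14 (AK063975) at 0.53. Those below were RLK4 (AK111650) at -1.39 (SE 0.27), a WIP2 homologue (AK071104) at -1.37, AK106478 at -1.12, UDP-glucose dehydrogenase (AK104003) at -0.95 and a splicing factor (AK070292) at -0.93. Each had a limma adjusted p of 0.997. The probes called in TW16-4 and not in TW16-69 were therefore not shown to differ between the lines.

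The photosynthesis list was the only one of 34 whose shift differed between the lines, lower in TW16-69 (median difference -0.17 log2, 7 of 28 genes above 0, 0 called by either adjustment, camera adjusted p = 3.42e-04). With an estimated correlation it had an adjusted p of 0.978. Of the 9 members at the scanner limit on some array, 4 were at the limit in both channels on all 4 arrays, among them the photosystem I subunit AK058788, plastocyanin (AK070447) and the chlorophyll binding protein AK066762. No fold is given for these 4, and the other 5 were at the limit in fewer channels or arrays. Without saturated probes the adjusted p was 0.931, and without TW16-69 replicate 2 it was 0.0856. The medians of the 19 unsaturated members differed by 0.02 (SE 0.05) on the replicate 1 arrays and -0.15 (SE 0.12) on the replicate 2 arrays. Each SE is approximate and comes from the spread over these probes within a day. It takes the probes as independent and holds no variation between arrays or plants. Other lists passed for the difference without 1 array. They were the Calvin cycle without TW16-4 replicate 1 (lower in TW16-69, 0.0047), and ribosomal proteins (0.0075), peroxidases (0.0114) and epidermal wax genes (0.0345), all higher, without TW16-69 replicate 1. Without TW16-69 replicate 2, ribosomal proteins (1.28e-05), epidermal wax genes (0.0132) and phenylpropanoid genes (0.0371) were lower.

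The level of each probe over infected and mock leaves together was also compared between the lines. An anthocyanidin reductase homologue (AK072654), an enzyme of flavonoid metabolism, was at -1.98 log2 in TW16-69 relative to TW16-4 (SE 0.31, n = 2 per line), with -1.95 and -2.02 on the replicate 1 and 2 days. The other lower described probes of smallest unadjusted p were AK103226 at -1.37, a homeodomain factor (AK100250) at -1.06, AK107099 at -0.85 and a glutamate carboxypeptidase AMP1 homologue (AK063229) at -0.81. The higher ones were AK064484 at 1.01, the auxin-regulated IAA8 homologue (AK063854) at 0.69, AK073263 at 0.66, AK072207 at 0.57 and an RLK4 homologue (AK111550) at 0.56. None passed (limma adjusted p = 1 for each), and 0 probes were called, with 57 at an unadjusted p under 0.05. This fit recovered 0% of simulated changes of 2 log2, so its 0 calls do not show equal levels.

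With the replicate block 23 probes were called for level, 11 higher and 12 lower in TW16-69, and all 23 had the same sign on both days. That fit leaves 1 residual degree of freedom against 20.84 prior ones, so the spread of a probe is taken largely from all probes. It gave 25 false calls on simulated data with 50 changed probes at each of 4 sizes. Beside these it recovered 16, 50, 50 and 50 of the changes of 0.5, 1, 1.5 and 2 log2. How many of the 23 are false is not known. The 23 included AK072654 (adjusted p = 8.97e-08), AK103226 (0.0018), AK064484 (0.0038), AK100250 (0.0108) and AK107099 (0.0409). Outside the naming rule, and chosen after their values were seen, were AK064014, 6.22-fold higher in TW16-69 (2.64 log2, limma adjusted p = 2.54e-08), AK061190, 4.71-fold lower (-2.23, 2.54e-08), and the germin-like protein GER5 (AK065284), 2.17-fold higher (1.12, 0.0011). GER5 differed by 1.82 log2 between the mock samples and by 0.47 between the infected ones. AK064014 differed by 2.66 and 2.60 in the same order, and AK061190 by -2.20 and -2.28. Without the block the level difference of GER5 had an SE of 0.60 (limma unadjusted p = 0.123). Its log2 ratio of infected over mock was higher on the replicate 2 day by 1.88 in TW16-4 and 3.25 in TW16-69. In fits on the mock or the infected channels alone with the same block, also chosen after, AK061190 passed (0.0442 and 0.0359) and AK072654 missed (0.0573 and 0.102). AK103226, AK064484, AK100250, AK107099, AK064014 and GER5 missed as well (0.985 and 1.00 for each). These fits used an estimated correlation of -0.42 between the 2 channels of a spot, against 0.80 without the block. Their misses therefore do not show that a difference is absent in either channel. Cytosolic ribosomal proteins, part of the translation machinery, were shifted higher in TW16-69 (34 genes, median 0.15 log2, 0 called by either adjustment, camera adjusted p = 0.0136, and an adjusted p of 0.867 with an estimated correlation). The acidic protein P0 (AK064857) was at 0.34, with 0.68 and 0.0033 on the replicate 1 and 2 days, and a 60S protein (AK063806) at 0.29, with 0.55 and 0.04. The list had an adjusted p of 0.0168 with the replicate block, 0.845 with the direction turned without TW16-4 replicate 1, 0.370 without TW16-69 replicate 1 and 0.614 without TW16-69 replicate 2. Disease resistance (NBS-LRR) proteins, which include many receptors of pathogen molecules, had a median of -0.06 (106 genes, camera adjusted p = 0.0530), with YR5 (AK100303) at -0.38 and YR48 (AK065798) at -0.35, neither past the test, and the list passed without TW16-69 replicate 2 (0.0256).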

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

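In this part, the tests reported below were written down before their own results were computed, but after the list difference had been seen, and the fit without saturated probes was chosen after that.

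The photosynthesis light reactions differed between the lines by a median of -0.1684 log2, TW16-69 minus TW16-4, in the set test of the difference itself (camera adjusted p = 3.42e-04). Of the 28 members, 9 were at the scanner limit on some array, and without them the adjusted p was 0.9312, so saturation may account for the call. Dye bias of the replicate 2 day stays open for the small shift that is left: the unsaturated members had medians of -0.0736 and -0.0741 Cy5 over Cy3 on the arrays of that day, whose dyes run opposite ways, with 0.0736 the smaller in size. A difference between the lines was not excluded, since the unsaturated medians differed by 0.0249 (SE 0.0507) on the replicate 1 day and -0.148 (SE 0.125) on the replicate 2 day. These SE come from the spread over probes within a day and hold no variation between arrays or plants. Of the 9 members, 4 were at the limit in both channels on all 4 arrays, so their response was not measured, and the other 5 were at the limit in fewer channels or arrays.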

How the results depend on the processing

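In this part, the fits without saturated probes, on each day alone and on single channels with the replicate block were chosen after the data were seen. Of 602 alternative values of 36 called results of named probes, a probe counting once per comparison, 421 kept their sign and stayed past the threshold, 181 kept their sign and missed it, and 0 changed sign. The called probes had the same sign on all arrays of their comparison, so the 0 was largely fixed in advance. Some fits repeat one another, such as the deposited value table and the deposited log ratios, so the 602 are not separate checks. The counts that moved by more than 1.5 times are given here as TW16-4, TW16-69 and mean response. With the deposited log ratios or the deposited value table they were 0, 0 and 24, and the probes 2-fold on both arrays were 87 in TW16-4 and 134 in TW16-69 against 43 and 54. The replicate block, which is also the day block, gave 84, 166 and 218, and 23 for level. The dye term gave 0 in TW16-69 and 30 in the mean, scaling 24 in TW16-4 and 0 in TW16-69, median centring 12 in TW16-69, no filter on dim probes 2 in TW16-4, outlier-marked spots kept 1 in TW16-4 and 1 in TW16-69, and TW16-69 alone 7. Unadjusted p under 0.05 with a 2-fold change gave 74 and 102 in the lines, 62 for the difference and 11 for level. The mean response gave 664 on the replicate 1 day alone and 85 on the replicate 2 day alone, and level gave 1 in the mock and 1 in the infected channels alone with the block. Leaving out each array gave 0 to 12 in TW16-4, 0 to 11 in TW16-69, 21 to 90 in the mean, and 0 for the difference and for level; a lone array of a line is then assumed to vary like the other line's. The difference stayed at 0 in every fit at the adjusted threshold. Gene lists past the threshold were 2 in TW16-4, 0 in TW16-69 and 1 each in the mean, difference and level. They were 0 everywhere with an estimated correlation or fry. The test with an estimated correlation has little power on 4 arrays, so a miss there does not show that correlation made a call. For photosynthesis in TW16-4 the estimate of 0.0926 was above the preset, and this stays open. The count was 1 in TW16-4 with the deposited log ratios and 2 in TW16-69 with the block. It was 2 in the mean with the dye term (calcium signalling upward and epidermal wax downward). Without saturated probes it was 0 in TW16-4 and in the difference. Leaving out each array gave 1 to 5 lists in TW16-4, 2 to 4 in TW16-69, 1 to 4 in the mean, 1 to 4 in the difference and 0 to 1 for level. The cause of these moves was not tested in this part. The fits that leave out an array have fewer arrays, but their counts rose as well as fell. Those without saturated probes have fewer photosynthesis members. Why the senescence list in TW16-4 went from a camera adjusted p of 0.0445 to 0.0744 without saturated probes was not tested. Signs turned for AK064178 (-0.0079 without background correction, -0.0013 with scaling, -0.0093 on the replicate 2 day, -0.0880 to 0.0894 leaving out each array), AK069301 (-0.0163 with median centring, -0.0165 on the replicate 2 day) and eIF4G AK062438 (0.0709 on the replicate 2 day, against -0.28 over all arrays), all uncalled. Photosynthesis in TW16-4 had adjusted p from 4.82e-09 to 0.6651 and ribosomal proteins in level from 2.51e-05 to 0.8446 leaving out each array, the highest with the direction turned. Slide or scan day is the same fit as the replicate block, and the mean over probes of a gene was not run because each accession has 1 probe. Background medians of 44 to 69 against spot medians of 193 to 297 limit ratios of dim probes, and leaving them out gave 11, 3 and 58.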

Other observations

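In this part, the 12 further lists, the fits on each day alone and the tests of a fixed dye bias, of opposite line responses and of the day differences in response size were chosen after the results were seen.

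The 12 lists of regulators and transporters were written after the values were seen, and several were prompted by called probes that they hold, so their set tests do not show a shift apart from those probes. In the mean response 28 MAP kinase cascade genes had 2 rises, 20 values above 0 and a median of 0.08 log2 (camera adjusted p = 1.20e-05, and 0.510 with an estimated correlation). The 34 NAC transcription factors had 3 rises (OsNAC3, OsNAC4 and OsNAC5), a median of 0.0051 and a mean of 0.21 (0.0035, and 0.510 with an estimated correlation). The 39 AP2 and DRE-binding factors had 3 rises and a median of 0.02 (0.0205, and 0.510), and the 30 protein phosphatases 2C had 2 rises and a median of 0.04 (0.0109, and 0.535). The 41 amino acid and peptide transporters had 0 calls and a median of -0.04 (0.0408 downward, 0.0592 with the replicate block and 0.535 with an estimated correlation). None of the 12 differed between the lines (the smallest camera adjusted p was 0.862), and the lists of MYB, zinc finger, bHLH and bZIP factors, ABC and sugar transporters, glycosyltransferases and aquaporins had adjusted p from 0.0732 to 0.789 in the mean response.

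On the replicate 2 arrays the log2 ratios of the lines ran opposite over all probes (Spearman -0.6843 across probes). Of the probes 2-fold on both of these arrays, 43 went the same way and 7 opposite ways. A wrong dye label on 1 of those arrays is argued against, since of 36 probes changed 2-fold on all 4 arrays the share that kept its sign was 1. A dye bias fixed for each probe is argued against by a coefficient of -0.0018 between the TW16-69 arrays, which had the same dyes. Opposite responses of the lines that repeat in both replicates are argued against by the coefficients between replicates within a line, the larger of which was 0.0056. A dye bias particular to the replicate 2 day and opposite responses in the replicate 2 plants alone may each remain for the small ratios. They cannot be told apart, since line and dye ran together on that day.

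The size of the response differed between the replicate days in a like way in both lines. Of 71 probes 2-fold in the mean of the 4 arrays, 70 of them higher, 53 had day differences of the same sign in both lines, with a Pearson coefficient of 0.7919 across probes. DRE-binding protein 1B was higher on the replicate 2 day by 0.91 log2 in TW16-4 and 0.93 in TW16-69, the CCD1 homologue AK111852 by 2.43 and 2.42, and AK109382 was at -0.87 and -0.93, lower on that day. Scatter of single arrays would leave the day differences of the lines unrelated. Dye bias of the replicate 2 day would make them run opposite. The same 0.7919 argues against either as the whole cause. The 71 probes are not independent, though, and each day difference rests on 1 array per line and day. The argument is therefore weaker than 71 separate probes would make it. Dye bias of the replicate 1 day may remain, since both of its arrays had the infected sample in Cy5 and such a bias would move both lines alike (the SD of the day difference averaged over the lines was 0.887). The plants of a replicate and its processing day cannot be told apart either, since each replicate number had 1 processing day, so a difference in infection or handling between sets stays a hypothesis. The mean response called 664 probes on the replicate 1 arrays alone, where a dye bias shared by the lines counts as response, and 85 on the replicate 2 arrays alone, whose dyes ran opposite, so these counts do not compare the response of the days.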
